A study of Mus musculus with 2 samples.

How the data were processed

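H3K4me1 ChIP-seq was carried out on liver of B6NCrl mouse embryos at embryonic day 16.5, in 2 biological replicates of 1 group, each a pool of male and female embryos, with DNA fragments of 300 to 500 bp. Replicate 2 joined technical replicates 1 and 2 and came from 41 embryos, per the labels; the labels give no number of embryos for replicate 1.

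The authors deposited 4 peak lists in narrowPeak format on mm10: a list per replicate, a list called on both replicates' alignments together (the pooled list) and a replicated list derived from the other 3, per the text deposited with them. The rule of the replicated list, the aligner, the peak caller and their versions are not given in the sources used here. Each peak carries the authors' enrichment, a ratio or fold value of the peak whose denominator the deposited text does not state. Each also carries −log10 of a p-value and of a q-value, as the authors' caller gave them; the smallest −log10 p was 2.01 in the deposited list of replicate 1 and 2.04 in that of replicate 2, so peaks with p at or below about 0.01 were listed. Of the peaks, 9.01% in replicate 1 and 11.6% in replicate 2 had a q above 0.05. Peak lists hold no read counts, so the depth of each library is unknown, and a place without a peak is a place without a call and not a place without the mark.

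Coordinates are 1-based on mm10. Sequence came from the GRCm38.p6 reference and genes from the GENCODE M21 basic annotation; no peak of the 4 lists ended beyond the end of its chromosome, and chromosome 19 peaks held 0 unknown bases. Chromosomes 1 to 19, X and Y were used, with 21938 protein-coding genes. Overlaps were computed with bedtools 2.31.1 and all else with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, with figures from matplotlib 3.10.9.

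Peaks were shared when they overlapped by at least 50% of either peak. The share that covered length alone gives was taken from 100 circular shifts of a list along each chromosome (20 for alternatives). Peak bases were assigned in order to promoters (1 kb on each side of any transcript start of the annotation, non-coding genes included), exons, introns and intergenic DNA of all annotated genes. Protein-coding start sites were split by observed over expected CpG of 0.6 or more in the surrounding 1 kb (CpG-rich) or less (CpG-poor), and the share with a peak was taken every 100 bp within 5 kb. For each protein-coding gene the share of its locus covered by peaks was computed per replicate, the locus being the gene body with 10 kb on each side; the value given is the mean ± SD over the 2 replicates, and for a list the median over members in each replicate gives the SD.

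The 18 gene lists cover erythroid transcription factors, erythroid globin, haem and membrane genes, hepatic transcription factors, hepatocyte plasma proteins, hepatocyte metabolic enzymes, haematopoietic stem and progenitor, megakaryocyte, myeloid and granulocyte, lymphoid, Kupffer cell and macrophage, endothelial, stellate and mesenchymal, biliary, neural, muscle, epidermal and gut epithelial, housekeeping, and pluripotency and germline genes. They hold 308 genes, of which 307 were measured. A list's median was placed among 10000 random lists of the same size matched on locus length in 10 bins, and the list stood apart at a percentile of 2.5 or less or 97.5 or more. Neighbouring genes of a list can share peaks. A locus share also does not tell peaks of the gene from peaks of a neighbour within the 10 kb. At a number of named genes the strongest replicated peak lay outside the gene, among them Slc4a1, Creb3l3, Apoa2, F2, Hpd, Gp9, Stab1, Lyve1 and Pou5f1. Differences in median between 4 pairs of lists were tested by permutation across genes (100000 resamples, two-sided) with Benjamini-Hochberg adjustment over the 4.

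The genes named follow a rule fixed together with the lists: from each list the 3 members with the highest mean covered share and the 1 with the lowest, the genes under the 10 widest domains, the nearest genes of the 5 strongest replicated peaks and of the 3 strongest peaks seen only in each replicate, and the 5 list members with the largest difference between the replicates. Other genes are named with a statement that they were chosen after their values were seen. Domains are replicated peaks merged across gaps of up to 1 kb.

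Sites of 18 consensus sequences were counted on both strands in non-promoter replicated peaks and in flanks of equal width 5 kb away that touched no peak of any list. The ratio of densities was divided by that of the reversed, not complemented, consensus, which has the same base composition. Its SE is a delete-one-chromosome jackknife over 20 chromosomes, a ratio was apart from 1 beyond 1.96 SE, and no ratio is given with under 20 reversed sites, a minimum chosen after the data were seen. The reversed GATA consensus (RATAGW) also matches some GATA sites, AGATAG or TGATAG followed by A or T. These shared sites draw the normalised GATA ratio toward 1, so plain densities are given beside it. Gaps of 100 to 600 bp between neighbouring peaks were compared in the same way with the peaks beside them.

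The steps were tested on simulated data, after a first analysis of the real data. The overlap step found 59.9% of simulated peaks shared where 59.6% were. The list test, on lists of 16 among 21938 genes, called 4% of unchanged lists and 88% of lists with 4 times the coverage, so a smaller difference can pass unseen. The list comparison gave p below 0.05 for 6.5% of 200 unchanged pairs and 69.5% of pairs with 4 times the coverage. The motif step, on 20 simulated chromosomes, gave 1.48 where sites were planted for a ratio of 1.52 and 1.01 ± 0.0290 where none were. The planted site was AGATAA, which the reversed GATA consensus does not match, in random bases without repeats. The simulation therefore did not test the overlap of the reversed consensus with GATA sites, or the effect of repeats. The test of replicate ratios of lists, used in the closing part, called 6.5% of unchanged lists of 20 and 90% of lists with 2 times the bases in 1 replicate.

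The alternatives were the authors' q of 1e-05 or lower, other overlap rules, equal numbers of peaks, promoters of 2.5 kb, a CpG threshold of 0.75, a 50 kb window around the start site, the gene body alone, the replicated list, matching on GC content, flanks 10 kb away, gaps of 100 to 300 bp, merging across 3 kb and each replicate alone. Leaving soft-masked repeats out of the motif counts and gaps, and the stricter peaks for the X chromosome, were added after the data were seen. Left out were the peaks on contigs (1 in each replicate) and the signal tracks and control libraries, which were not analysed here. With 1 group, no test between conditions applies.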

Results

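H3K4me1, the monomethylation of lysine 4 on histone H3 that marks enhancers and the flanks of promoters, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the liver of B6NCrl mouse embryos at embryonic day 16.5. At this age the liver is the main site of red blood cell formation and also holds hepatocyte-lineage cells. The study had 1 group of 2 biological replicates, each made from liver pooled over male and female embryos. Replicate 2 came from 41 embryos and combined technical replicates 1 and 2, and the number of embryos behind replicate 1 is not given in the labels. No second condition was profiled, so the comparisons were between the 2 replicates and between genes, regions and sequences within them. Replicate 1 had 115909 peaks over 61.1 Mb (median width 337 bp) and replicate 2 had 92088 peaks over 44.4 Mb (median width 324 bp), a mean of 103998 ± 16844 peaks (SD, n = 2). A list called on both replicates together had 98341 peaks and the authors' replicated list had 79595 peaks over 49.1 Mb (median width 423 bp). Read depth is unknown from peak lists, so no counting interval on reads can be given, and a library with more reads can yield more peaks.

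Most strong H3K4me1 peaks lay at the same places in both replicates. The strongest replicated peak (13.4-fold enrichment) lay on chromosome 19 from 5846122 to 5850297, at the 3′ end of Frmd8 and over its antisense gene Frmd8os, and each replicate covered it fully. The start of the non-coding gene Neat1, named after the position was seen, lies beside it. The next 4 were an intergenic peak on chromosome 9 from 106397399 to 106398510, with Dusp7 as the nearest gene 29323 bp away; an intergenic peak 2625 bp upstream of Smad6, an inhibitor of bone morphogenetic protein signalling (chromosome 9, 64023272 to 64026095); a peak centred 747 bp from the start site of Kcnk7 (chromosome 19, 5703836 to 5706392); and a peak centred 1841 bp upstream of Tbc1d24 that also overlaps Ntn3 (chromosome 17, 24205595 to 24209211). Their enrichment was 13.1, 13.1, 12.9 and 12.8, and 96.5% to 100% of each was covered in both replicates. Enrichment is the authors' own value per peak and is used to rank and describe peaks within a list and, by correlation, to compare peaks shared by the replicates. Of the strongest peaks seen in only 1 replicate, those of replicate 1 lay nearest to Klf3 (377 bp, intergenic, 111419 bp from the start site), Sox12 (1146 bp, 48.3% covered in replicate 2, short of the overlap rule) and Emc7 (260 bp, intronic), and those of replicate 2 nearest to Fgd2 (961 bp, 91.7% covered in replicate 1 by a pair of peaks, neither of which met the overlap rule), Kat6a (390 bp, intronic) and Top2b (465 bp, intronic). Their enrichment was 8.73, 7.49 and 7.43 in replicate 1 and 7.20, 6.42 and 6.01 in replicate 2. The medians of the strongest decile of all peaks were 6.93 and 6.12, so a few strong peaks were called in 1 replicate only.

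Of replicate 1 peaks, 55.3% overlapped a replicate 2 peak by at least 50% of either peak (64092 of 115908 on the main chromosomes), and of replicate 2 peaks 79.0% overlapped a replicate 1 peak (72704 of 92087). Shifting a list along its chromosomes gave 2.58% and 3.34% on average over 100 shifts, with maxima of 2.98% and 3.98%. The covered bases had a Jaccard index of 0.536 against 0.0115 after shifting. Across the 64092 pairs of overlapping peaks, enrichment in the replicates correlated with a Spearman rho of 0.577 and a Pearson r of 0.621 on log2 values; this is across peaks, which are not independent replicates. Recovery followed strength: 27.9% of the weakest decile of replicate 1 peaks and 99.1% of the strongest decile were found in replicate 2, and 63.7% and 99.8% the other way. Peaks seen only in replicate 1 (51816) or only in replicate 2 (19383) had median widths of 243 and 227 bp, against 521 and 378 bp for shared peaks, and none reached 2 kb. Shared peaks had 1.32 and 1.20 times the median enrichment of these. At the authors' q of 1e-05 or lower the count ratio of replicate 1 to replicate 2 widened from 1.26 to 1.59.

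**Figure D1:**
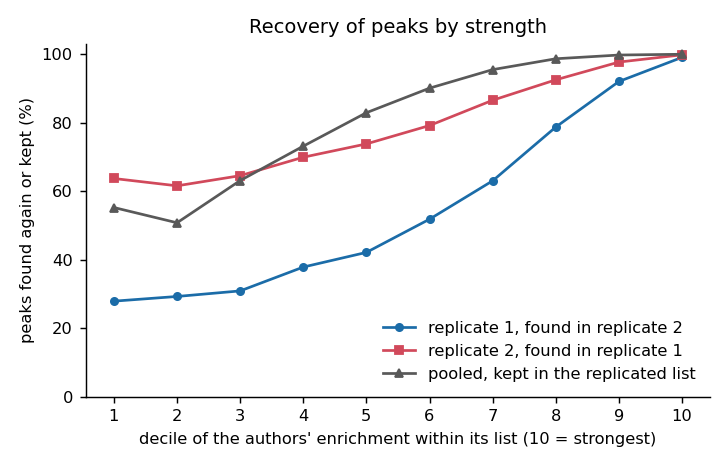
Share of peaks found in the other replicate, or kept in the replicated list, by decile of the authors' enrichment within each list (x axis, 10 = strongest; y axis, percent). Recovery reached 99.1%, 99.8% and 100% in the strongest decile of replicate 1, replicate 2 and the pooled list, and was 27.9%, 63.7% and 55.3% in the weakest.

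The replicated list kept the wider and stronger part of the pooled list. It held 80.9% of the pooled peaks; kept peaks had a median width of 423 bp and a median enrichment of 3.54, against 209 bp and 2.75 for the 18745 peaks left out. Of the kept peaks 83.3% overlapped peaks of both replicates (95% exact binomial interval 83.1 to 83.6, counting error only). A further 11230 overlapped a peak of replicate 1 only, 1882 of replicate 2 only and 164 of neither. Of the peaks left out, 0 overlapped both replicates at 50% and 699 did so at 1 bp. The rule behind the list is not stated in the labels or the deposited text.

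H3K4me1 was concentrated around genes. Promoters, taken as 1 kb on each side of any annotated transcript start, non-coding genes included, held 19.9 ± 0.0824% of peak bases (SD, n = 2), 4.56 times their share of the chromosomes. Exons held 5.04 ± 0.0825% (1.73-fold) and introns 56.0 ± 0.313% (1.39-fold). Intergenic DNA held 18.99 ± 0.478%, which was 0.363 of its share. With promoters widened to 2.5 kb on each side their part was 37.8% (3.73-fold) and the exonic part 3.15% (1.33-fold).

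Around start sites the mark sat beside the start and not on it at CpG-rich promoters. Of 10081 genes with a CpG-rich promoter, 8.52 ± 3.65% had a peak at the start site itself (SD, n = 2), 36.0 ± 6.33% had a peak 600 bp upstream and 41.0 ± 6.18% had a peak 1100 bp downstream. In each replicate the start site was the lowest point within 1 kb, at 11.1% and 5.94%, and the downstream maximum was 45.4% and 36.7%. The 11857 genes with a CpG-poor promoter had less of the mark and little of this shape, with 9.45 ± 2.28% at the start site and a maximum of 11.5 ± 2.46% at 200 bp upstream. With peaks of the authors' q of 1e-05 or lower, all 4 values fell, to 3.33%, 23.9%, 4.74% and 5.94% for the start site and the maximum of the CpG-rich and then the CpG-poor group.

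**Figure D2:**
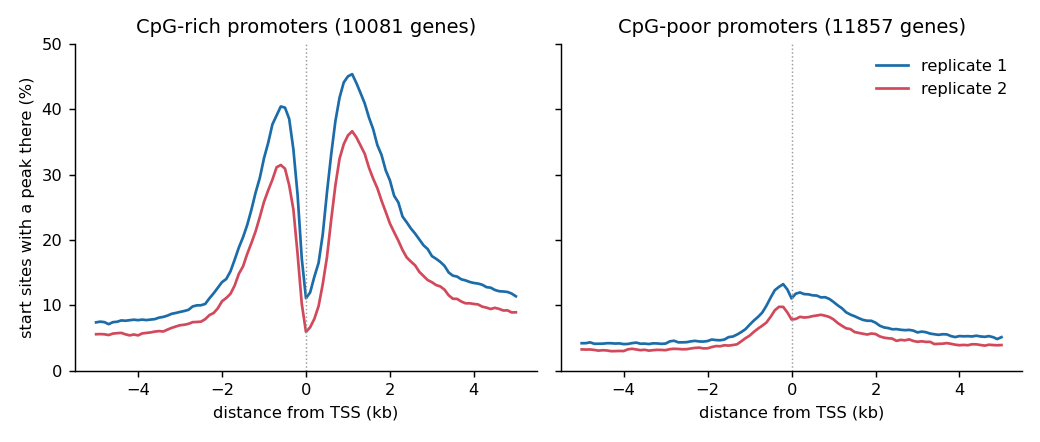
Share of protein-coding start sites with an H3K4me1 peak (y axis, percent) at each distance from the start site (x axis, kb; negative is upstream), for CpG-rich and CpG-poor promoters, with a line per replicate. At CpG-rich promoters both replicates fall to 11.1% and 5.94% at the start site between maxima upstream and downstream, and at CpG-poor promoters both stay below 14%.

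Erythroid transcription factors had the broadest H3K4me1 of the 18 lists. The locus of Zfpm1, which encodes the GATA1 cofactor FOG1, was covered over 78.2 ± 2.07% of its length (SD, n = 2; gene body and 10 kb on each side), that of Gfi1b, a repressor needed for red cell and platelet formation, over 50.01 ± 4.62%, and that of Klf1, the activator of adult globin genes, over 46.7 ± 7.30%. The median over 14 erythroid transcription factors was 32.4 ± 3.94%, against 2.54% for all 21938 protein-coding genes, and 12 of the 14 were in the top decile of genes (above 18.9%). Sox6, a repressor of embryonic globin genes with a very long body, was lowest at 5.70 ± 0.988%. The median of this list was at percentile 100 of 10000 random lists of the same size matched on locus length, in both replicates and in all alternatives. Zfpm1 lies on chromosome 8 from 122282141 to 122337251, Gfi1b on chromosome 2 from 28609450 to 28621982 and Klf1 on chromosome 8 from 84901928 to 84905291; the strongest replicated peak at Klf1 was centred 1514 bp upstream of its start site (84899580 to 84901248, enrichment 7.40).

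The genes of the red cell's globin, haem and membrane machinery were also broadly covered. Slc4a1, the band 3 anion exchanger (chromosome 11, 102348824 to 102366203), was covered over 45.5 ± 4.78% of its locus, with its strongest peak centred 3087 bp upstream; Ermap and Tspo2, both erythroid membrane proteins, had 34.9 ± 4.36% and 33.3 ± 3.22%. The list median was 16.8 ± 2.48% over 24 measured members, at percentile 100 in both replicates and in all alternatives. All 24 had a peak in both replicates and 11 were in the top decile of genes, while Spta1, erythroid alpha-spectrin, was lowest at 2.17 ± 0.183%. The alpha-globin gene Hba-a1 had 32.1 ± 6.30% and the beta-globin gene Hbb-bs 9.72 ± 2.96%, a pair named after its values were seen and not tested. Ahsp had no entry under that symbol and was not measured.

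Hepatocyte genes were covered less, and unevenly. The labels name liver and no sorted cell type, and the share of each cell type is not given. Low coverage of a list therefore does not show that its own cells lack the mark. Among hepatic transcription factors, Rxra, the shared partner of liver nuclear receptors (chromosome 2, 27676440 to 27762957), had 33.9 ± 4.27%, Creb3l3, a regulator of lipid genes, 23.4 ± 2.81% and Foxa3 22.5 ± 3.66%, while Onecut1 had 0.788 ± 0.431% and no replicated peak. All 20 had a peak in both replicates, and their median of 4.44 ± 2.70% was at percentile 82.3. It was at 13.6 with matching on GC content and 40.8 with the stricter peaks. Among plasma proteins, the apolipoproteins Apoa2 and Apoa1 had 20.2 ± 2.72% and 13.3 ± 3.83% and prothrombin (F2) 15.9 ± 3.04%, but Kng1 had no peak in either replicate. The strongest replicated peaks at Apoa2, Apoa1 and F2 lay outside the gene, centred 3375, 1417 and 6398 bp upstream of its start site. Whether such peaks belong to these genes or to neighbours was not tested. The median over 22 was 2.23 ± 1.77%, at percentile 32.7. Albumin (Alb) and alpha-fetoprotein (Afp), which define this lineage and are named after their values were seen, had 1.26 ± 1.02% and 2.02 ± 1.09%, and transthyretin (Ttr) had no peak. Among 24 metabolic enzymes, Acsl1, which activates long-chain fatty acids, had 30.4 ± 5.61%, Glul, glutamine synthetase, 18.0 ± 3.75% and Hpd, a tyrosine-degrading enzyme, 13.0 ± 0.741%, whereas the urea cycle enzyme Cps1 had none, nor had Cyp27a1, Cyp2e1, Cyp3a11, Otc and Tdo2, named after their values were seen. The median was 1.18 ± 0.337%, at percentile 6.94. None of the 3 lists stood apart from random lists, in the main setting or in any alternative.

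Of 4 further blood lists, megakaryocyte genes were covered most and lymphoid genes least. Megakaryocyte genes had a median of 9.64 ± 2.19% over 14 members (percentile 98.5), led by the platelet glycoproteins Gp1ba (35.7 ± 2.94%) and Gp9 (27.8 ± 4.16%) and by Nbeal2, needed for alpha granules (18.0 ± 0.434%), with none at Gp6; on the gene body alone the percentile was 96.6, inside the range of random lists. Haematopoietic stem and progenitor genes had a median of 5.77 ± 2.40% over 16 (percentile 97.8), led by Gata2 (18.7 ± 2.98%), Runx1 (15.2 ± 3.50%) and Lmo4 (10.1 ± 4.81%), with Mecom at 0.118 ± 0.0687%. That call did not hold in replicate 2 alone (95.3), the replicated list (96.8), with random lists matched on GC content (90.4), with a window of 50 kb around the start site (82.0) or with the stricter peaks (80.4). Myeloid and granulocyte genes had a median of 2.20 ± 0.792% over 14 (percentile 43.7), with the neutrophil proteases Elane (21.5 ± 6.48%) and Prtn3 (17.2 ± 4.78%), neighbours whose loci share a strongest peak, and the PU.1 gene Spi1 (15.5 ± 3.64%) highest and Ctsg without a peak. Lymphoid genes had a median of 0.652 ± 0.507% over 17 (percentile 11.9), with Cd79a (24.3 ± 3.08%), Lck (11.8 ± 3.05%) and Gata3 (3.26 ± 0.505%) highest and Cd3e at 0; with matching on GC content they fell below random lists (percentile 1.92).

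Kupffer cell and macrophage genes were the least covered of the 18 lists. The share of these cells in the liver is not given, so the low coverage does not show that they lack the mark. Of 15 members 10 had no peak in either replicate, among them Adgre1, a macrophage surface marker. The genes that did were led by Hmox1 (12.4 ± 4.91%) and the iron exporter Slc40a1 (6.41 ± 2.45%), followed by the receptor Csf1r (1.70 ± 0.606%). The median was 0 in both replicates, at percentile 1.37 of random lists. This call was lost in replicate 2 alone (percentile 3.82) and with the replicated list (4.10), the gene body alone (4.36), a window of 50 kb (5.85) and the stricter peaks (18.1).

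In lists of other liver cells and other tissues single genes such as Notch2 and Eng carried the mark broadly, while the list medians were not apart from random lists. Endothelial genes had a median of 2.28 ± 0.462% over 16 (percentile 47.5), with Eng (20.8 ± 6.05%), Stab1 (14.2 ± 1.15%) and Lyve1 (13.4 ± 2.80%), the last a marker of sinusoids, highest and Emcn at 0. Stellate and mesenchymal genes had 0.846 ± 0.289% over 16 (percentile 6.48), with Lhx2 (4.46 ± 1.29%), Col1a1 (3.39 ± 2.34%) and Pdgfrb (2.14 ± 0.512%) highest and Col3a1 at 0. Biliary genes had 0.595 ± 0.700% over 12 (percentile 20.2), with Notch2 (22.3 ± 1.62%), Sox4 (14.7 ± 12.2%) and Hnf1b (2.94 ± 1.92%) highest and Cftr at 0. The list of neural genes had 0.490 ± 0.626% over 22 (percentile 17.5; Dlx2 12.9 ± 2.62%, Neurog2 10.8 ± 2.28%, Lhx1 7.70 ± 2.19%, Ascl1 0), that of skeletal and cardiac muscle genes 0.470 ± 0.363% over 18 (percentile 7.34; Ckm 7.23 ± 2.04%, Tnnt2 4.07 ± 1.505%, Nkx2-5 2.68 ± 1.36%, Myf5 0), that of epidermal and gut epithelial genes 0.258 ± 0.244% over 15 (percentile 13.9; Vil1 12.9 ± 2.30%, Sftpc 4.97 ± 1.72%, Cdx2 1.51 ± 1.15%, Krt1 0) and that of pluripotency and germline genes 0.507 ± 0.717% over 12 (percentile 10.9; Pou5f1 11.6 ± 2.51%, Lin28a 5.38 ± 1.36%, Ddx4 4.03 ± 0.764%, Dppa4 0). None of these 7 lists stood apart in the main setting. With matching on GC content the neural, muscle and epidermal lists fell below random lists (percentiles 1.33, 0.340 and 0.300). The neural list also did so with the 50 kb window (2.36) but was at 73.4 on the gene body alone, and the muscle list with the replicated list (2.02).

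Housekeeping genes were broadly covered too. Their median was 20.9 ± 4.82% over 16 members (percentile 99.99, and 99.97 or higher in all alternatives), with the ribosomal protein gene Rpl13a (42.5 ± 5.80%; chromosome 7, 45125558 to 45128761), Gapdh (36.1 ± 5.596%) and beta-actin (Actb, 32.8 ± 5.74%) highest. Pgk1, on the X chromosome, was lowest at 1.09 ± 0.651%. Of all 21938 genes 28.3% had no peak in either replicate, and 66.0% had more of their locus covered in replicate 1 than in replicate 2. The list members that differed most between the replicates were Sox4 (23.3% in replicate 1 and 6.06% in replicate 2), the embryonic globin gene Hba-x (38.3% and 26.0%), Bcl11a (36.2% and 24.96%), Cebpa (20.2% and 9.82%) and Klf1 (51.8% and 41.5%), each higher in replicate 1. The gene lists (307 measured genes), the 4 comparisons of lists, the rule for naming genes and all but 3 of the varied settings were chosen before the data were examined.

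**Figure D3:**
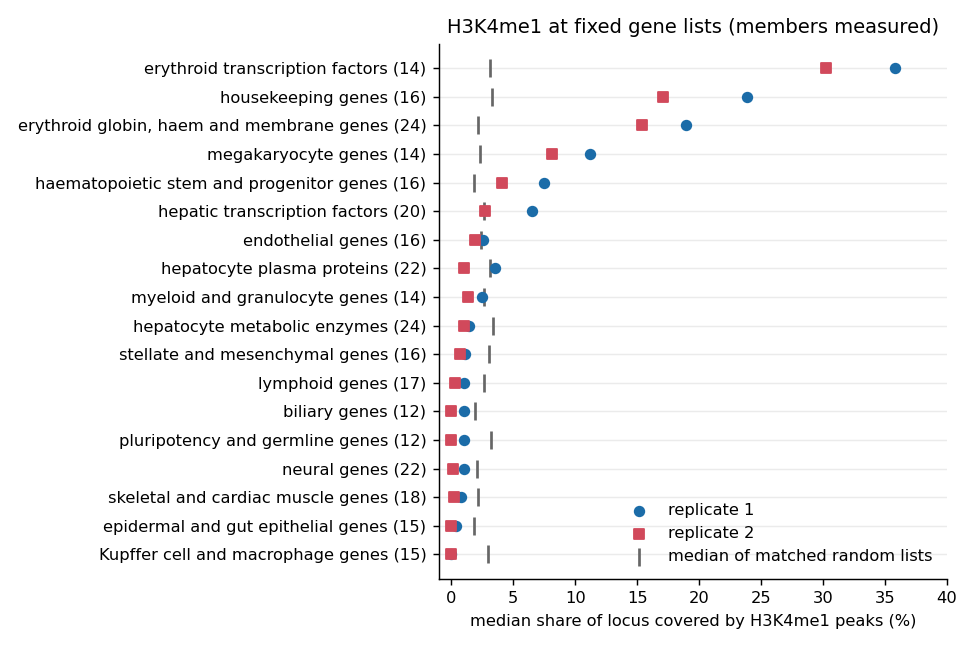
Median share of the locus covered by H3K4me1 peaks (x axis, percent) for each fixed gene list (y axis, measured members in parentheses), with a point per replicate and a tick at the median of matched random lists. Erythroid transcription factors (35.8% and 30.2%) and housekeeping genes (23.9% and 17.0%) lie farthest above their ticks, and Kupffer cell and macrophage genes lie at 0 in both replicates.

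Erythroid regulators exceeded lymphoid genes, and hepatic regulators exceeded neural genes, in the comparisons fixed beforehand. Erythroid transcription factors were covered 31.7 percentage points more than lymphoid genes (medians 32.4% of 14 genes and 0.652% of 17; permutation test across genes, two-sided, p = 3e-05, Benjamini-Hochberg adjusted p = 6e-05 over 4 comparisons). Hepatic transcription factors were covered 3.95 points more than neural genes (4.44% and 0.490%; permutation p = 0.00247, adjusted p = 0.00329). The difference shrank to 0.284 points with the stricter peaks (permutation, adjusted p = 0.0405) and was 5.53 and 2.60 points in replicates 1 and 2 alone. Plasma protein genes fell by 14.5 points below erythroid globin, haem and membrane genes (2.23% and 16.8%; permutation p = 3e-05, adjusted p = 6e-05). Metabolic enzymes and plasma proteins were not told apart by the test (1.18% and 2.23%; permutation p = 0.229, adjusted p = 0.229). Their order changed with the 50 kb window (difference 0.100 points). The smallest of these p-values are near the lowest that 100000 permutations can give, and the tests compare genes within these libraries, where genes are not replicates. The permutations did not match genes on locus length or GC content. Among random lists matched on length, hepatic transcription factors and neural genes were at percentiles 82.3 and 17.5, neither apart. With matching on GC content as well they were at 13.6 and 1.33.

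The widest H3K4me1 domain lay over Zfpm1. Replicated peaks merged across gaps of up to 1 kb made 41828 domains with a median width of 788 bp, of which 377 were at least 10 kb wide. The Zfpm1 domain ran from 122284347 to 122333793 on chromosome 8 (49447 bp, 6 peaks), from the first intron over most of the gene body; replicate 1 covered 98.1% and replicate 2 covered 96.9% of it. The long annotated gene Gm20388 spans the same place. The next widest lay over March3, a ubiquitin ligase gene (45990 bp; chromosome 18, 56865228 to 56911217), Foxo3, a forkhead factor of the erythroid list (35383 bp; chromosome 10, 42239167 to 42274549), Stk24 (32739 bp), Bcl2l1, which encodes the survival factor BCL-XL (29824 bp; chromosome 2, 152800109 to 152829932), Ranbp10 (29670 bp), Elmsan1 (29140 bp), Sptb, erythroid beta-spectrin (28598 bp; chromosome 12, 76659607 to 76688204), Rbm38 (28209 bp) and Hectd4 (27349 bp). Replicate 1 covered more of each of these than replicate 2, from 72.3% and 63.7% at March3 to 90.4% and 83.9% at Rbm38. Merging across 3 kb raised the number of domains of 10 kb or more to 1541, and the stricter peaks lowered it to 109.

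Each of the 10 widest domains held at least 1 composite of an E-box part (CTG) and a GATA site, which domains this wide can hold by width alone. TAL1 and GATA1 bind such composites together. The Zfpm1 domain had 8, 4 of them with the 8 bp spacer and 4 with the 7 bp spacer, beside 99 GATA sites and 22 KLF sites; an example was CTGCTGCAGTCTGATAG on the plus strand of chromosome 8 from 122302072 to 122302088. The Hectd4 domain had 6, Bcl2l1 had 5, March3 and Rbm38 had 4 each and Sptb had 3, among them CTGCTGTGTCTAGATAA on the minus strand of chromosome 12 from 76673903 to 76673919. The Foxo3 and Elmsan1 domains had 2 each and the Stk24 and Ranbp10 domains had 1 each. Of the 5 strongest peaks, those nearest to Dusp7 and Tbc1d24 had 1 each and the others had 0. Flanks held 0.0335 and 0.0369 composites per kb with the 8 and 7 bp spacers, so domains this wide hold some by width alone, and the GATA sites of the Zfpm1 domain (2.00 per kb) were as dense as in flanks (1.98). These counts are a description of single regions, without a test.

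**Figure D4:**
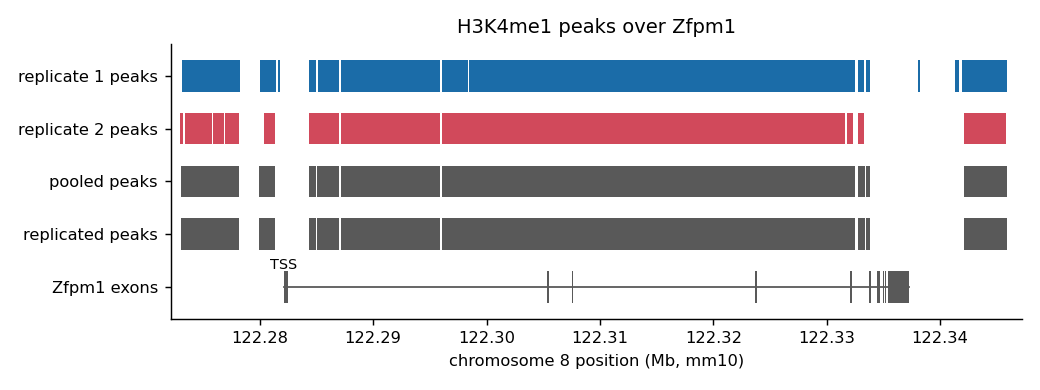
H3K4me1 peaks of replicate 1, replicate 2, the pooled list and the replicated list (bars, a lane each) over the Zfpm1 gene, with its exons and start site in the lowest lane; the x axis is the position on chromosome 8 in Mb of mm10. All 4 lists cover the stretch from 122284347 to 122333793 nearly without gaps and leave the start site free.

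Away from promoters, H3K4me1 peaks were rich in composite E-box and GATA sites and in KLF sites. The E-box and GATA composite with the 8 bp spacer (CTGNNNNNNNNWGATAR) was 2.35 ± 0.146 times as dense in peaks as in flanks 5 kb away after division by the same ratio for the reversed sequence (jackknife SE over 20 chromosomes, above 1 on 20 of 20), and the composite with the 7 bp spacer 2.05 ± 0.202 times. The NR5A and ERR site had 2.05 ± 0.141, falling to 1.45 ± 0.133 with soft-masked repeats left out and to 1.28 ± 0.0447 in plain density. The simple GATA site had 1.39 ± 0.0105, the KLF site 1.37 ± 0.0401, the RUNX site 1.33 ± 0.0454, the FOXA site 1.24 ± 0.0462, the PU.1 and ETS site 1.17 ± 0.0331 and the NF-E2 and AP-1 site 1.14 ± 0.0314. Each of these 9 differed from 1 by more than the threshold on its SE, in both replicates and in all alternatives. Sites of HNF4 (1.24 ± 0.126), C/EBP (1.13 ± 0.0960) and ONECUT1 (1.19 ± 0.119) did not pass in the replicated list. In plain density HNF4 (1.29 ± 0.0831) and C/EBP sites (1.27 ± 0.0790) were denser in its peaks than in flanks. ONECUT1 sites were less dense there (0.697 ± 0.0475). HNF4 did pass in each replicate alone (1.29 and 1.34), with flanks 10 kb away (1.26) and with repeats left out (1.304). C/EBP passed in replicate 2 alone (1.31) and ONECUT1 in replicate 1 alone (1.22), where its plain density was lower in peaks than in flanks (0.674 ± 0.0463). Among comparison factors of other tissues, MEF2 (1.301 ± 0.176; 1.39 and past the threshold with flanks 10 kb away, where its plain density ratio was 0.989) and POU sites (0.913 ± 0.0895) did not pass. The neural bHLH site was below 1 (0.824 ± 0.0460) but rose above it, to 1.31 ± 0.0946, with soft-masked repeats left out, so its direction depends on repeats. HNF1, CTCF and REST had under 20 reversed sites in peaks or flanks and no normalised value. The plain density of CTCF sites in peaks was 1.25 ± 0.174 times that in flanks. Peaks had a GC content of 48.7% and flanks 44.9%, and the plain density of GATA sites, not divided by the reversed sequence, was nearly equal in both (1.04 ± 0.00848), as was that of FOXA sites (1.04 ± 0.0276), whose normalised excess reflects fewer reversed sites in peaks (0.838).

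**Figure D5:**
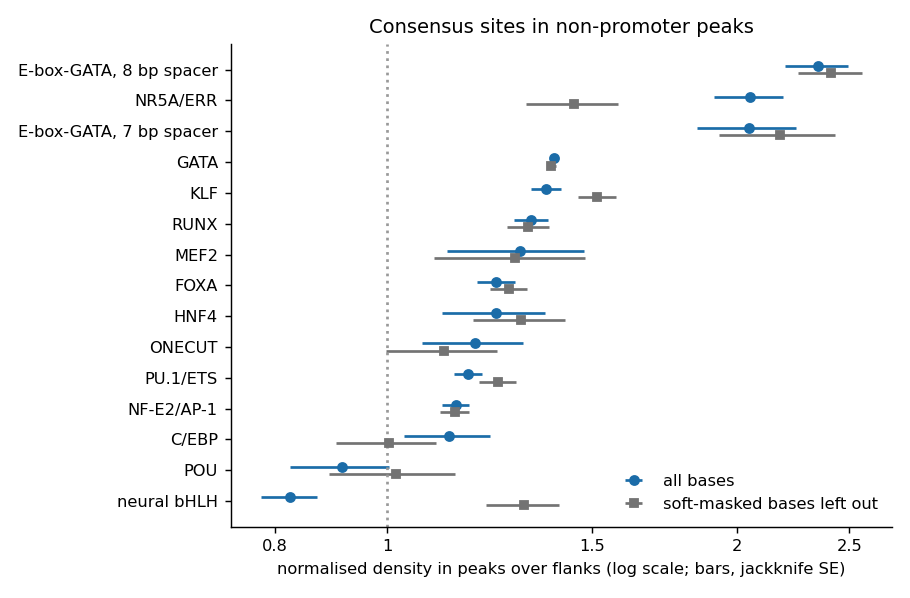
Density of consensus sites in non-promoter replicated peaks over flanks 5 kb away, normalised to the reversed consensus (x axis, log scale; bars are the jackknife SE over 20 chromosomes), with all bases and with soft-masked bases left out. The E-box and GATA composite with the 8 bp spacer lies farthest from 1 (2.35), followed by the NR5A and ERR site and the 7 bp composite (2.05 each, but 1.28 and 1.86 in plain density), and the neural bHLH site changes side, from 0.824 to 1.31.

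Gaps between neighbouring peaks differed from the peaks beside them. In 18831 gaps of 100 to 600 bp the composite with the 8 bp spacer had a normalised density 1.47 ± 0.124 times that of the adjoining peaks. Its plain density was 1.32 ± 0.111 times theirs. The normalised ratio was only 1.36 in the gaps of replicate 2 and 1.00 in those of replicate 1, neither apart from 1. The simple GATA site (0.869 ± 0.0112) and the RUNX site (0.737 ± 0.0405) were less dense in gaps after normalisation, although gaps are poorer in GC (41.9% against 48.3%) and the plain density of GATA sites in them was 1.29 ± 0.0169 times higher. The PU.1 and ETS site was at 1.17 ± 0.0672, lost in each replicate alone (1.04 and 1.12). The NR5A and ERR site (0.506 ± 0.0593) and the neural bHLH site (1.59 ± 0.165) were also apart from 1, and both calls were lost with soft-masked repeats left out (1.11 and 0.888). The 7 bp composite (0.828), KLF (1.034), NF-E2 and AP-1 (0.993), HNF4 (1.58), FOXA (1.01), C/EBP (1.15), ONECUT1 (0.897), MEF2 (0.943) and POU sites (1.02) were not apart from 1. CTCF, whose bound sites are free of nucleosomes, had 127 sites in gaps, a plain density 3.50 ± 0.547 times that of the peaks beside them.

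Chromosome 11 carried the densest H3K4me1 and the X chromosome the sparsest of those with peaks. Chromosome 11 had 73.4 ± 9.70 peaks per Mb (SD, n = 2) and chromosome 19 had 66.6 ± 9.05. Chromosome 14 had 30.0 ± 5.95, the lowest autosomal value, and the median autosome had 43.4. The X chromosome had 6.17 ± 2.65 and the Y chromosome had 0 in both replicates. Replicate 1 had 1.20 to 1.33 times as many peaks as replicate 2 on the 19 autosomes and 1.87 times as many on the X chromosome (1314 and 702). With the authors' q of 1e-05 or lower the ratio was 2.74 on the X chromosome (167 and 61) and 1.59 on the autosomes together. Each replicate had 1 peak on an unplaced or unlocalised contig, which was left out.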

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

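Leaving soft-masked bases out, and the stricter peaks on the X chromosome, were tests chosen after the results were seen; the others were planned. Of 330 values under alternatives 264 kept their call or stayed within their spread, some of them crossing the middle of the random lists, 17 lost a call, 16 gained a call, 32 moved and 1 reversed. All 16 alternatives of the list comparisons kept their side of the significance threshold, but hepatic regulators less neural genes shrank to 0.284 points with stricter peaks and metabolic less plasma protein genes turned to 0.100 points with the 50 kb window. Both erythroid lists and housekeeping genes stood apart in all 7 alternatives each. No paired analysis was possible because there is only 1 group. Unknown read depth limits all counts of peaks. HNF1, CTCF and REST had too few reversed sites for a normalised value, so the 330 values hold none for them. The plain density ratio of CTCF sites in peaks was 1.55 ± 0.272 with the stricter peaks and 1.07 ± 0.155 with flanks 10 kb away. It was 1.22 ± 0.116 in replicate 1 alone and 1.12 ± 0.119 in replicate 2 alone. The cause of the changes below was not tested unless the construction shows it.

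Peaks with the authors' q of 1e-05 or lower, a smaller set by construction, numbered 32957 and 20692; 51.3% and 87.7% overlapped, with a Jaccard index of 0.502 and a rho of 0.484. They gave an X ratio of 2.74, 20.8% promoter, 5.14% exonic and 55.2% intronic bases, 3.33% and 23.9% at the start site and maximum of CpG-rich and 4.74% and 5.94% of CpG-poor promoters, and 109 domains of 10 kb or more with the widest at 47429 bp. Overlap was 59.1% and 83.4% at 1 bp, 40.2% and 50.6% at 50% of both peaks (rho 0.635), and 63.2% and 72.9% with equal numbers of peaks (Jaccard 0.555). At 1 bp 84.1% of replicated peaks were found in both replicates. Promoters of 2.5 kb took 37.8% of bases, exons 3.15%, introns 43.4% and intergenic DNA 15.7%. With a CpG threshold of 0.75 the CpG-poor maximum was 15.6%. Merging across 3 kb gave 1541 domains of 10 kb or more and a widest one of 80235 bp.

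Percentiles of haematopoietic stem and progenitor genes were 82.0 with the 50 kb window, 96.8 with the replicated list, 80.4 with stricter peaks, 90.4 with GC matching and 95.3 to 98.8 with single replicates. Megakaryocyte genes were at 96.6 on the gene body alone. Kupffer cell and macrophage genes were at 5.85, 4.36, 4.10 and 18.1 with the 50 kb window, the gene body, the replicated list and stricter peaks, and at 1.53 to 3.82 with single replicates. Calls gained below random lists were lymphoid (1.92), neural (1.33), muscle (0.340) and epidermal genes (0.300) with GC matching, neural genes with the 50 kb window (2.36) and muscle genes with the replicated list (2.02). Without a change of call, hepatic transcription factors moved to 13.6 with GC matching and 40.8 with stricter peaks, and neural genes to 73.4 on the gene body alone.

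In peaks, HNF4 passed at 1.29 and 1.34 in replicates 1 and 2, 1.26 with flanks 10 kb away and 1.304 without soft-masked bases. ONECUT1 passed at 1.22 in replicate 1, C/EBP at 1.31 in replicate 2 and MEF2 at 1.39 with flanks 10 kb away; the plain density ratios of ONECUT1 (0.674) and MEF2 (0.989) there were below 1, so these passes come from fewer reversed sites in peaks. The neural bHLH site reversed to 1.31 without soft-masked bases. In gaps, replicate 1 gave 1.00 for the 8 bp composite, 0.650 (apart) for the 7 bp composite, 1.04 for PU.1 and 1.84 (apart) for HNF4; replicate 2 gave 1.36 for the 8 bp composite and 1.12 for PU.1. Shorter gaps gave 1.72 for C/EBP (apart), and without soft-masked bases NR5A was at 1.11 and the neural bHLH site at 0.888, neither apart.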

Other observations

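All tests in this part, and the 27 gene families behind its first paragraphs, were chosen after the results of the report had been seen; each family was fixed before its own values were computed, and its members are named after their values were seen.

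Beyond the fixed lists, replicative histone, ribosomal protein and erythropoietin signalling genes were broadly covered by H3K4me1. The EPO receptor pathway, the survival signal of red cell precursors, had a median covered share of 26.5 ± 8.04% over 7 genes (SD, n = 2; percentile 99.98 of random lists matched on locus length), with Pim1 (48.3 ± 5.84%), Cish (44.6 ± 7.75%) and Stat5a (28.3 ± 5.90%) highest, Jak2 lowest (7.66 ± 0.274%) and 6 of 7 in the top decile of genes. Genes of terminal erythroid maturation, which clear organelles and proteins from the red cell, had 15.7 ± 6.19% over 7 (percentile 99.5), led by the ubiquitin ligase gene Ube2o (45.5 ± 7.36%) and the autophagy kinase gene Ulk1 (31.4 ± 2.78%). Both of these lists were written with the erythroid results in view, so they are not independent of them. Ribosomal protein (Rpl13a), apolipoprotein (Apoa1, Apoa2), cytochrome P450 (Cyp2e1, Cyp3a11, Cyp27a1), keratin (Krt1), Serpina and numbered zinc finger families also hold members of the fixed lists, whose values were already known. The same is true of other families, among them KLF (Klf1), solute carrier (Slc4a1) and interleukin genes (Il7r). Replicative histone genes had 24.2 ± 1.09% over 67 (percentile 100), ribosomal protein genes 14.4 ± 2.64% over 80 (100), with Rpl3 at 42.6 ± 6.21%, STAT and JAK genes 13.2 ± 2.23% over 10 (99.9) and ubiquitin-conjugating enzyme genes 9.12 ± 2.20% over 37 (99.99). The random lists matched to histone and ribosomal protein genes had low medians, 0% and 0.953%. These 6 families stood above random lists in both replicates and in the replicated list. They are not separate results, since some share members. Stat5a is in the EPO and the STAT and JAK families, and Ube2o in the maturation and the ubiquitin-conjugating families. Histone genes lie in clusters and share loci, so their percentile overstates their number.

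Few peaks were called at sensory receptor genes. How well reads align to such similar genes was not examined, so the absence of calls does not show absence of the mark. Neighbouring members can share loci. Of 1134 olfactory receptor genes 1091 had no peak in either replicate and only Olfr65 was in the top decile of genes (24.6 ± 0.301%; chromosome 7, 103903487 to 103908650). Olfr65 and its neighbour Olfr66 (18.2 ± 1.99%; 103879443 to 103886252) lie beside the beta-globin cluster, where Hbb-bh1 ends at 103843164. Of 328 vomeronasal receptor genes 324 had no peak. Cytochrome P450 genes, many of them liver enzymes of later life, also lay below random lists (median 0 over 100 genes, 57 without a peak), although Cyp2w1 had 35.5 ± 4.34%. Apolipoprotein genes (10.7 ± 0.859% over 17, percentile 99.0; Apoc1 31.2 ± 3.73%, Apoe 25.8 ± 2.81%) and aminoacyl-tRNA synthetase genes (6.32 ± 2.08% over 35, at the threshold) stood above random lists on the mean, and keratin (percentile 1.87), Serpina (1.28) and numbered zinc finger genes (1.00) below, but none of these 5 did so in each replicate and the replicated list. The other 13 families were not apart, from fibroblast growth factor genes at percentile 5.10 to KLF genes at 96.3.

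The X chromosome had 1.87 times as many peaks in replicate 1 as in replicate 2, against at most 1.33 on an autosome. Weak peaks are lost first in the smaller list, and X peaks were weaker than autosomal peaks (median pooled enrichment 3.17 and 3.33). Of 1045 pooled X peaks 89.8% were found in replicate 1 and 54.4% in replicate 2, a ratio of 1.65. This ratio was above all 10000 draws of autosomal peaks matched on enrichment and width (median 1.34, 95% of draws from 1.28 to 1.40). Pooled enrichment and width therefore did not account for the whole difference. The draws were not matched on p or q, and read counts are unknown. Weaker statistical support of X peaks is thus not excluded as the whole cause. A different share of female and male embryos in the pools may contribute, but the labels give no shares and the Y chromosome, with 0 peaks, offers no value. No biological explanation was tested.

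Plasma protein genes had 1.74 times as many covered bases in replicate 1 as in replicate 2, hepatic transcription factors 1.43 times and metabolic enzymes 1.36 times, against 1.34 over all loci. For hepatic transcription factors lists matched on covered share reached this often enough (percentile 95.7, range of matched lists 1.23 to 1.45) for low coverage to be a candidate explanation. For plasma proteins the ratio was above the matched range (percentile 99.4, range 1.25 to 1.66), so few lists of like coverage reached it. The matched lists draw genes singly, while neighbouring members of a list can share peaks, so the range may be too narrow. The pattern was also seen in these same libraries, and the 18 lists were compared without adjustment. Low coverage is therefore not excluded as the whole cause there. A larger share of hepatocyte-lineage chromatin in replicate 1 cannot be told apart from other causes: the metabolic list was at percentile 74.4, neither above the matched range nor in its lower part. Haematopoietic stem and progenitor genes (ratio 1.65, percentile 99.98) and neural genes (2.02, percentile 97.9) were also above, 3 of 18 lists in all and 0 below, so the difference was not specific to hepatocyte genes.

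Fewer CpG-rich promoters had H3K4me1 at the start site than beside it, and poor recovery of GC-rich fragments could give such a dip. Coverage at the start site over the highest coverage within 2 kb was 0.208 ± 0.00827 (jackknife SE) at 10075 CpG-rich start sites, whose median GC content was 64.8%. At 6618 CpG islands more than 5 kb from any start site, with a median GC content of 61.6%, the same ratio was 0.897 ± 0.0333 (SE of the difference 0.0343). Coverage at these islands was low, from 4.83% at the centre to 5.38% at the highest point, and their GC content was slightly lower. The highest point beside CpG-rich start sites was 41.0%. With so little of the mark around the islands a dip can hardly show there. The comparison therefore cannot exclude loss of GC-rich fragments as the cause. Removal of nucleosomes, or a change to trimethylation of the same residue, at active start sites may account for the dip, as a hypothesis that peak lists of this mark alone do not test.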
